A study of Homo sapiens with 6 samples.

How the data were processed

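The arrays measured long non-coding RNA and messenger RNA in SKOV3, an established human ovarian carcinoma cell line. For each of the 6 samples, total RNA was labelled with Cy3 and hybridised to a 1-colour Agilent array. Cells had been transduced with a lentiviral vector for the β subunit of human chorionic gonadotropin (β-hCG), a placental hormone, or with a negative control vector. The titles place 3 arrays in each group, and the labels call them biological replicates, without saying whether they came from separate transductions. If they were passages of 1 transduced pool, the p-values measure only the spread between these cultures.

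The deposited values are log2 intensities, 1 column per array, as their range from 2.61 to 18.3 shows. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.7. The background correction, the normalization between arrays and the genome build are not given in the sources used here. The sorted values of the 6 columns differ by at most 0.123 log2 units at any rank, and by 0.0161 on average over ranks, as after quantile normalization. Such scaling removes any change that most probes share. The table has no detection or saturation flags, so dim probes were kept and no level was set as a detection limit. On each array 16.0% to 18.5% of the probes lay at or below the negative control row, which read 2.79 to 2.82. The number of arrays and the spread between them limit the precision.

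The table has 120932 rows. Of these, 120864 have custom probe identifiers that neither the table nor the gene tables used here pair with a gene. The other 68 are Agilent's control rows, which include 4 human GAPDH and PGK1 probes. The fixed lists of pathway, cell type and lncRNA genes, the counts of protein-coding and long non-coding genes, the β-hCG transcript, and the alternatives that need gene names or set tests were therefore not computed. Probes are given by identifier. The rule for named items, set before the data were examined, named called genes by fold change and needed gene symbols. In its place the 2 rises and the 2 falls with the lowest p-values are named, a choice made after the data were examined.

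The 120864 custom probes were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient for β-hCG minus control vector, all 6 arrays, no covariate and an intensity trend in the prior variance (lmFit, then eBayes). The fit had 4 residual degrees of freedom. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Adjusted p-values come from this two-sided limma test, except for the human control probes. These were compared with a two-sided exact permutation test, which cannot give a p under 0.1 with 3 arrays against 3, and its p-values were adjusted over the 4 probes with Benjamini-Hochberg. "Brighter probes" are the 60432 whose mean over the 6 arrays exceeded the median probe mean of 4.39. Principal components were taken over all custom probes.

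The fit was tested on simulated data that used the real probe means and within-group SDs of β-hCG and control arrays. Of the 120864 probes, 200 were changed, all drawn from the brighter probes. It called 6 of 50 probes changed by 1 log2 unit, 33 of 50 at 2 units, 43 of 50 at 3 units and 48 of 50 at 6 units, with 6 false calls. With 1 common SD of 0.146 it called 20 of 50 at 1 unit and 50 of 50 at each larger change. Alternatives fixed before the data were examined were 3 other scalings, 2 filters on dim probes, 2 variance models, array weights, the replicate number as a block, 3 other thresholds, and leaving out each array. A block for the 2 sets of arrays given by the order of 2 spike-in probes was added after the data were examined. Same-numbered arrays of both groups did not deviate together, so the numbers were not treated as pairs. The share of probes that agree in direction between replicate 1 and the other β-hCG arrays was set beside 20 simulations in which all arrays were unchanged and the controls shared.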

Results

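The series compared SKOV3 ovarian carcinoma cells carrying a β-hCG lentivirus with cells carrying a control vector, asking which long non-coding and messenger RNAs differ when the hormone subunit is overexpressed. β-hCG is the specific subunit of chorionic gonadotropin, which trophoblast normally secretes. There were 3 arrays per group. All arrays had nearly the same distribution of log2 intensities, with medians of 4.48 to 4.52 and 75th percentiles of 7.23 to 7.24. The custom probes carried no gene names here, so the transduced transcript was not identified among them, and no statement on named lncRNAs or pathways was made.

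One probe, CUST_142102_PI430048170, stood apart from every other probe on the array. It read 6.27 ± 0.08 (SD, n = 3) in control vector cells and 13.09 ± 0.11 (SD, n = 3) in β-hCG cells. The log2 fold change was 6.82 with a standard error of 0.07, a 113-fold difference with a 95% confidence interval of 101 to 127. Its adjusted p in limma was 1.13e-05. All 3 β-hCG arrays carried the rise, at 12.97, 13.14 and 13.16 on replicates 1, 2 and 3, against 6.18 to 6.34 on the control arrays. No other probe had all β-hCG arrays at least 3 log2 units above all control arrays. Its gene and genomic position are not known here.

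This was the only probe called, with 1 higher and 0 lower. The next lowest adjusted p in the limma fit was 0.167. Without adjustment, 15481 probes had p under 0.05, of which 8503 were higher and 6978 lower in β-hCG cells, where 6043 of the 120864 would be given by chance. The 3 other splits of the arrays that kept β-hCG replicates 2 and 3 together gave 7617 to 9665 such probes, and the 6 that parted them 2376 to 3046, so part of the excess follows these arrays rather than the group. In 20.6% of probes the groups did not overlap, where chance gives 10% and those splits gave 11.8% to 13.5% and 5.4% to 7.8%. An absolute log2 fold change of at least 1 was seen in 3126 probes, 1241 higher and 1885 lower, and all but 1 of these failed the test. In the simulated data, where all changed probes were brighter ones, only 6 of 50 probes changed by 1 log2 unit were recovered. A change of 1 log2 unit equals the fold minimum, so noise alone puts part of such probes below it. Most changes of this size in brighter probes would thus be missed, through the fold minimum, the within-group spread and the adjustment over all probes together. The simulation changed 200 probes, many of them strongly, which eases the Benjamini-Hochberg threshold for the rest. With only 1 probe called in the real data that threshold is stricter, so the simulated recovery rates are likely too high for these data. With 1 common SD of 0.146 for every probe, 20 of 50 were recovered.

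The falls with the lowest p-values belonged to brighter probes. CUST_143589_PI430048170 read 9.72 ± 0.02 in control cells and 9.17 ± 0.02 in β-hCG cells (SD, n = 3 each), a log2 difference of -0.55 with a standard error of 0.03. CUST_51626_PI430048170 read 8.82 ± 0.04 and 7.94 ± 0.10, a log2 difference of -0.88 with a standard error of 0.06. The second rise, CUST_94102_PI430048170, read 2.65 ± 0.02 in control cells, below the negative control row at 2.79 to 2.82, and 3.48 ± 0.05 in β-hCG cells (SD, n = 3 each), so its fold change is not given. None of the 3 passed, with an adjusted p of 0.167 each in the limma fit, although the groups did not overlap in any of them.

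**Figure D1:**
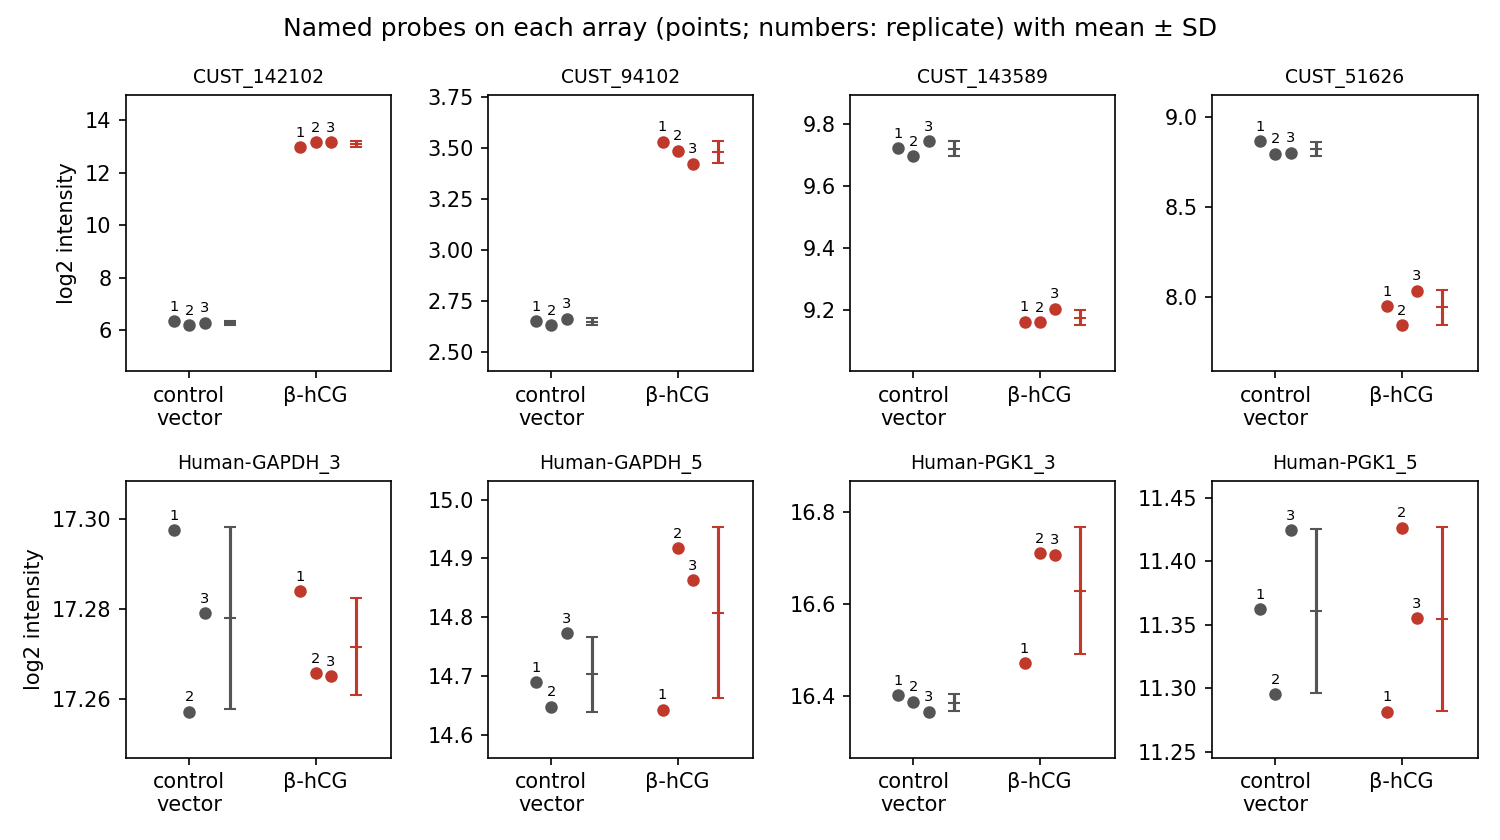
Log2 intensity of the 4 named custom probes (top) and the 4 human control probes (bottom) on each array; points are arrays with their replicate number, and the bar is the mean ± SD of 3 arrays. CUST_142102 separates the groups by 6.82 log2 units, while the PGK1 probe with suffix 3 is highest on β-hCG replicates 2 and 3; each panel has its own vertical scale.

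GAPDH and PGK1, both enzymes of glycolysis, were the only human genes that the row identifiers named. The GAPDH probe with suffix 3 read 17.28 ± 0.02 in control and 17.27 ± 0.01 in β-hCG cells (SD, n = 3 each; exact permutation p = 0.7), and the one with suffix 5 read 14.70 ± 0.06 and 14.81 ± 0.15 (SD, n = 3 each; exact permutation p = 0.4). The PGK1 probe with suffix 5 read 11.36 ± 0.06 and 11.35 ± 0.07 (SD, n = 3 each; exact permutation p = 0.8). The PGK1 probe with suffix 3 read 16.39 ± 0.02 and 16.63 ± 0.14, a difference of 0.24 log2 units (SD, n = 3 each; exact permutation p = 0.1, the smallest this design can give). Adjusted over these 4 probes, the lowest exact p was 0.4. The PGK1 probes differed in what they showed. On the suffix 3 probe, β-hCG replicates 2 and 3 both read 16.71, while replicate 1 read 16.47, close to the highest control array at 16.40.

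The 3 β-hCG arrays did not resemble one another equally. Replicate 1 correlated more strongly with the control arrays than with replicates 2 and 3 of its own group. Over all custom probes its r was 0.985 with each control array, and 0.981 and 0.982 with the other β-hCG arrays. Control arrays correlated with one another at 0.986 to 0.987, and β-hCG replicates 2 and 3 at 0.987. These correlations are across probes, which are not independent replicates. Among the 60432 brighter probes, replicate 1 differed at least 2-fold from a control array in 1414 to 1579 probes, where control arrays differed from one another in 1358 to 1495. Replicates 2 and 3 differed from the control arrays in 2769 to 3586 probes, and from replicate 1 in 2782 to 3250. They differed from each other in 1738.

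**Figure D2:**
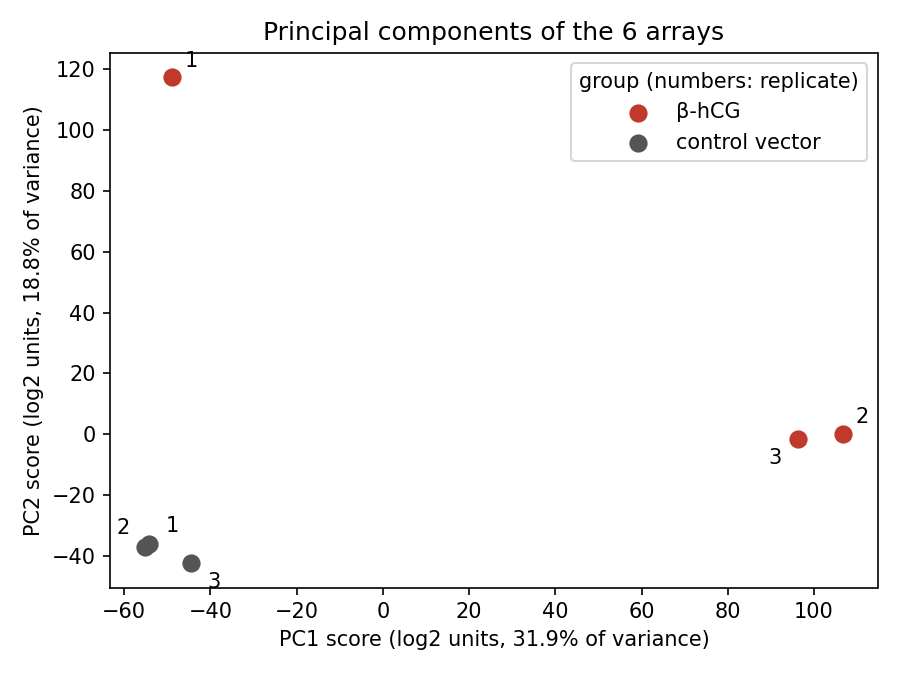
Scores of the 6 arrays on the first principal components of the custom probes, in log2 units, with 31.9% and 18.8% of the variance; colours are groups and numbers are replicates. On the first component β-hCG replicates 2 and 3 lie at 106.6 and 96.2, and replicate 1 lies at -48.9, within the control range. On the second component replicate 1 lies apart at 117.4, against -42.5 to -36.3 for the control arrays.

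The first principal component held 31.9% of the variance and placed replicate 1 at -48.9, within the control range of -55.1 to -44.6. The second component separated replicate 1 from the other 5 arrays. The median SD of a brighter probe was 0.098 log2 units among the 3 control arrays and 0.152 among the 3 β-hCG arrays.

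The count of called probes rested on β-hCG replicate 1. Without it, limma called 999 probes, 275 higher and 724 lower, with a median absolute log2 fold change of 1.35. The β-hCG group is then replicates 2 and 3 alone, the same arrays that the order of 2 spike-in probes sets apart, so this fit does not separate group from array set. Most of the falls, 459 of 724, were in brighter probes, against 18 of 275 rises. In replicate 1, 735 of the 999 probes differed from the control mean in the same direction, a share of 73.6%, but by a median of 0.16 log2 units, and 79 of them by at least 1. The same control arrays entered both differences. In 20 simulations of unchanged arrays against shared controls, the 999 probes with the lowest p agreed in direction in 72.8% to 77.7%. That range holds the observed share, but the simulated probes had no real shift, while the 999 had a median of 1.35. The simulations therefore cannot tell how much of the observed share the common controls gave. With separate control arrays for each difference, brighter probes at least 1 log2 unit from a control on both replicates 2 and 3 were taken. Of these, 53.7% to 59.0% differed the same way in replicate 1, against 44.0% to 56.0% for a control array in its place. The share was higher for replicate 1 in all 6 choices of controls, which reuse the same 3 arrays. Swapping 2 control arrays mirrors the share of the control in its place, so those shares are not 6 separate references.

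**Figure D3:**
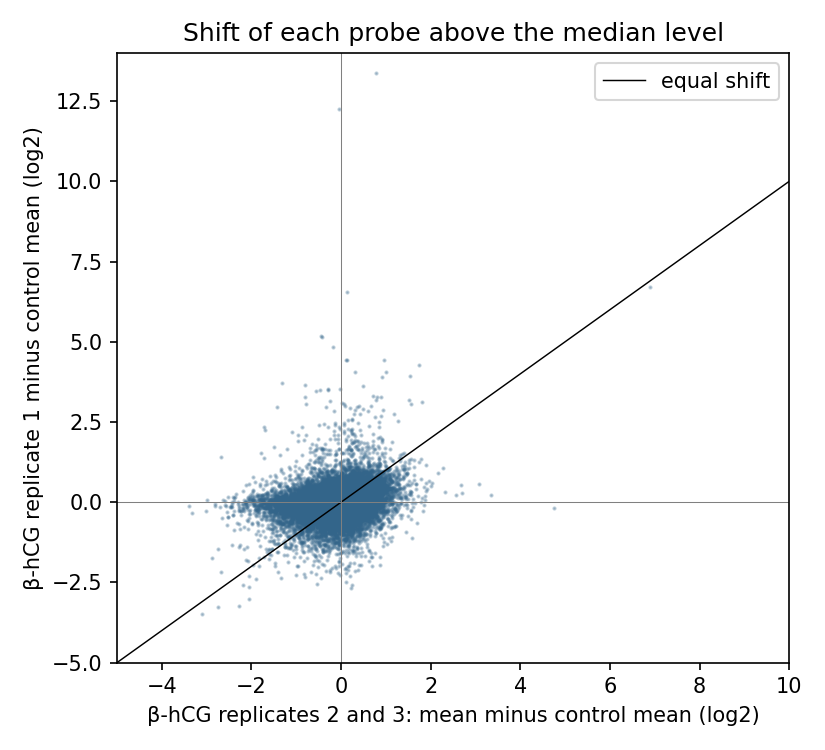
Shift of each of the 60432 brighter probes from the control mean, in log2 units, in the mean of β-hCG replicates 2 and 3 (horizontal) and in replicate 1 (vertical); each point is a probe and the line marks equal shifts. CUST_142102 lies alone near the line at the upper right, at 6.70 on the vertical axis, and most probes shifted along one axis lie near 0 on the other.

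Some of the spike-in control probes also set β-hCG replicates 2 and 3 apart. The E1A probes report adenoviral transcripts of Agilent's spike-in mix, which Agilent's protocol adds to the RNA before labelling and which does not come from the cells. Probes n11, n9 and a107 were chosen after their values were seen. Probe n11 read below probe n9 on the 3 control arrays and on β-hCG replicate 1, with differences of -0.352 to -0.329. On β-hCG replicates 2 and 3 it read above n9, by 0.25 on both. Spike-in probe a107 read 5.56 to 5.82 on the first 4 arrays, and 6.37 and 6.28 on replicates 2 and 3. Without these 3 probes and the GAPDH and PGK1 rows, 53 control rows remained. Replicates 2 and 3 lay together above or below the other 4 arrays in 18 of them, and so did control replicate 1 with β-hCG replicate 1, where chance gives 7.1. Over the 7 remaining E1A rows the counts of these pairs were 3 and 4, so the rows not chosen did not single out replicates 2 and 3. By the order of n11 and n9, the first set of arrays held both groups and the second held β-hCG cells only. Within the first set, CUST_142102_PI430048170 was 6.70 log2 units above the control mean, with 1 array against 3. CUST_143589_PI430048170 differed by -0.56 and CUST_51626_PI430048170 by -0.87 there. With the set as a block, limma gave these 3 probes adjusted p-values of 6.17e-04, 0.0116 and 0.0376, and only the first probe met the fold minimum. These p-values compare 1 β-hCG array with 3 controls. That fit called 500 probes, all higher, and its set effect called 765, of which 72 were higher and 693 lower on replicates 2 and 3. Both counts rest on replicate 1, whose spread is assumed equal to that of the other arrays. The group effect compares replicate 1 with the controls, and the set effect compares replicates 2 and 3 with replicate 1. A probe lower on replicates 2 and 3 in the set effect is thus equally one higher on replicate 1. Over all 500 the median control level was 2.78, and only 27 of the 500 were brighter probes.

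**Figure D4:**
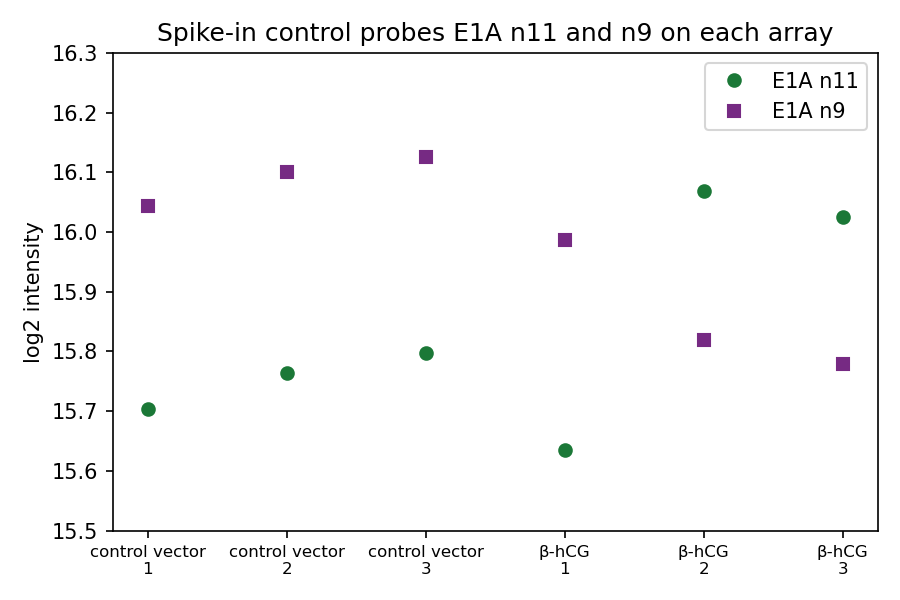
Log2 intensity of the E1A spike-in probes n11 and n9 on each array; the vertical axis does not start at 0. Probe n9 is the brighter on the control arrays and β-hCG replicate 1, and n11 is the brighter on β-hCG replicates 2 and 3.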

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

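All tests in this part were chosen after the results were seen, except the count of called probes in the other splits and the fit without each array.

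Control rows outside the comparison held 3 signals that were higher on every β-hCG array than on every control array. DCP_22_9 was higher by 1.42 log2 units, carried mostly by replicate 3 at 6.18, ERCC-00144_60 by 0.069 and ETG10_234183 by 0.064. Their control means of 2.76, 2.81 and 2.89 lie at or near the negative control row at 2.79 to 2.82, so these differences are not read as fold changes. Chance alone would give 3.2 such rows among the 64, and 5 others were lower on every β-hCG array. These were Mouse-GAPDH_5 (-1.17 log2 units), Mouse-PGK1_3 (-0.61), ERCC-00062_278 (-0.37), E1A n9 (-0.23) and Mouse-GAPDH_3 (-0.13). Their control means of 5.70 to 16.1 lie well above the negative control row. In Mouse-GAPDH_5 the fall was mostly on replicates 2 and 3, at 3.97 and 4.09, while replicate 1 read 5.52.

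The pattern most in need of follow-up is that β-hCG replicate 1 lies with the control arrays by correlation and on the first principal component. On the second component it lies apart from them. For a control array carrying the wrong label, the called probe was examined, and it was 6.70 log2 units above the control mean there. That probe was chosen with replicate 1 counted as β-hCG, so a rise there was built in and this test alone cannot decide. In the 9 other splits no probe had a gap above 3.27 log2 units, so choosing a probe this way did not give such a gap elsewhere. The fit without replicate 1 also called this probe, at 6.89 log2 units, but among 999 probes. Singling it out from these used replicate 1. The probe's linear excess on replicate 1 was 88.1% of that on replicates 2 and 3. On this 1 probe, that argues against a large share of control RNA mixed into replicate 1, but not against a small share. Whether replicates 2 and 3 were processed apart from the other 4 arrays stays open. Outside the 3 E1A rows chosen for the split and the GAPDH and PGK1 rows, they lay together above or below the others in 18 of 53 control rows, and another pair, control replicate 1 and β-hCG replicate 1, also in 18, where the test asked for at least 2 times the highest other pair. Over the 15 brighter DCP rows they had 4, against 10 for another pair. Of 9 tallies made, 6 included the chosen rows or the GAPDH and PGK1 rows and decide nothing. The n11 minus n9 difference, chosen because it showed the split, left a gap of 0.576 log2 units between the sets, against a range of at most 0.023 within a set. A difference in the cultures, such as passage or clone, stays open and untested, and how much of the shift of replicates 2 and 3 belongs to processing cannot be told, because no control array is in their set.

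In the called probe, the lowest β-hCG array lay 6.63 log2 units above the highest control array. The largest such gap of any probe in any of the 9 other splits of the arrays into 3 and 3 was 3.27. In the count of called probes, the real split gave 1 and the highest other split 0, and 10 splits are too few for a share under 0.05. Whether the probe reports the transduced transcript was not tested, as its gene is not known here.

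A separate pattern was probes bright on a single array. Over the 6 arrays, 691 probes read at least 3 log2 units above every other array, while 1 read as far below. Each array had 59 to 161 of them, and β-hCG arrays held 45.3%, which is consistent with spot faults or other events of single arrays that are unrelated to the group. Their median level on the other arrays was 2.78 to 2.92, near the negative control, and 1 of them read 17.3 on β-hCG replicate 1 and at most 5.00 elsewhere. No array read below 2.61, so a probe near that floor could not read 3 log2 units lower. The counts of bright and dim probes are therefore not comparable. No biological explanation was tested for this pattern.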

How the results depend on the processing

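The single called probe kept its direction and stayed past the threshold in all 16 alternative fits, with log2 fold changes of 6.70 to 6.89 and adjusted p-values up to 0.00900. The count of called probes was 1 in 16 of 20 alternatives, among them the 3 other scalings, both filters on dim probes and the replicate block (1 probe). The 3 other thresholds could give no other count, as the main limma fit had adjusted p-values of 1.13e-05 and then 0.167. The 3 scalings could change little, as the columns already had nearly the same distribution. These 6 alternatives are therefore weak support. Leaving out 1 array in turn gave counts from 1 to 999, where only the fit without β-hCG replicate 1 differed from 1. Without the intensity trend it was 2, with 1 fall added. With the spike-in split as a block, added after seeing the data, it was 500 over all probes and 52 over brighter probes, 50 higher and 2 lower, and these rest on replicate 1. Under the block, which sets 1 β-hCG array against 3 controls, and without replicate 1, where group and array set are the same, the other 3 named probes had an adjusted p under 0.05; neither fit is independent support for them. CUST_51626_PI430048170 also had one with both filters on dim probes. None of the 3 met the 2-fold minimum or was called in any fit, and no named probe changed direction. Same-numbered arrays deviated with correlations of 0.013, -0.018 and 0.017, so the numbers show no pairing. The excess of correlation of β-hCG replicate 1 with control arrays over that with its own group was 0.0040, and 0.0040 to 0.0053 in 5 alternatives. The 3 scalings among these are no test of it. Scaling to a common median or 75th percentile shifts each array by a constant, which cannot change a correlation. Quantile normalization could change little, as the columns already had nearly the same distribution. Only the filters on dim probes could move the value, and they gave 0.0053 and 0.0051. Probes near the negative control carry little information, and the table has no flags to separate them from expressed ones.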

Other observations

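The tests in this part were chosen after the results were seen. β-hCG replicate 1 may share a small part of the shift of replicates 2 and 3. With a different control array for each shift, so that no array was in common, the covariance over the brighter probes averaged 0.0143 over 6 choices of controls, with a range of 0.0086 to 0.0179. A control array in place of replicate 1 gave -0.0072 to 0.0072. The correlations were weak, 0.048 to 0.103. Among 1414 to 1626 brighter probes at least 1 log2 unit from one control array on both replicates 2 and 3, the median shift against another control array averaged 1.06 for those replicates and was 0.042 to 0.089 for replicate 1, against -0.056 to 0.056 for the remaining control array. The ranges overlap, but replicate 1 was the higher in all 6 choices, which reuse the same 3 control arrays and are not independent. Swapping 2 control arrays only reverses the sign of a value with a control array in place. These values, covariances and shifts alike, are therefore mirrored pairs and not 6 separate references. A small shared response to β-hCG would give this, and so would a partial technical likeness between the arrays; the data do not separate them.

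Separation of all 3 β-hCG arrays from all 3 control arrays was more frequent than in the other splits at a small gap, but not at a larger one. With a gap of at least 0.25 log2 units, 1232 brighter probes separated, 524 higher and 708 lower in β-hCG cells. The 3 other splits that kept replicates 2 and 3 together gave 549 to 863, and the 6 that parted them gave 184 to 225. With a gap of at least 0.5, the real split gave 166, those 3 splits 112 to 183 and the 6 others 23 to 39. With a gap of at least 1, the counts were 11, 2 to 18 and 3 to 9.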
